A study of Escherichia coli BW25113 with 40 samples.

How the data were processed

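RNA-seq libraries of Escherichia coli BW25113 were analysed from the raw gene counts that the authors deposited, 1 table of 4531 genes by 40 libraries. Per the submitters' processing notes, reads were trimmed with cutadapt 2.10 and aligned with Bowtie2 2.4.1. The genome build, the strand setting, the counting tool and the handling of reads that align to several places are not given in the sources used here. Counts of near-identical genes (rRNA, some tRNA, gadA and gadB, tufA and tufB) are therefore uncertain, as are those of overlapping genes, and no coordinates are given. Locus tags were matched to a K-12 gene table for names, classes and lengths. It covered 4526 tags, and the 5 unmatched ones held at most 0.00318% of the reads of a library. The table held 4236 protein-coding genes, 112 pseudogenes, 86 tRNA, 69 other non-coding RNA and 22 rRNA genes.

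rRNA genes were left out of all tests and library sizes, which left 4509 genes. A gene was called detected with at least 5 reads. Shares of reads carry 95% Wilson intervals, and a count of 0 was taken to allow 3 reads. Folds of genes at 0 in both libraries of an input take 3 reads over the 2 libraries together. In a single library, a count of 0 allows 1.37 and 0.982 CPM in the 5 ng libraries and 776 and 450 CPM at 100 fg. The relation of genes detected and of reads to log10 input was tested by two-sided permutation with 100000 resamples, adjusted over 6 tests by Benjamini-Hochberg. The replicate numbers of the gradient were not used to pair samples.

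The 12 gradient libraries were fitted together with edgeR quasi-likelihood (robust, TMM factors, filterByExpr with a minimum count of 10). This tested 1637 genes, each lower input against 5 ng and a slope on log10 input, two-sided, with Benjamini-Hochberg adjustment at 0.05 within each contrast. The fitted common biological coefficient of variation was 58.1%. The 14 gene lists were tRNA, tRNA inside rRNA operons, rRNA, small RNA, ribosomal protein, amino acid biosynthesis, flagella, RpoS general stress, heat shock, glycolysis and tricarboxylic acid cycle, ATP synthase, envelope, leader peptide and deleted genes. Those with at least 5 tested members were tested with limma camera at a preset correlation of 0.01, with Benjamini-Hochberg over lists and contrasts, and again with an estimated correlation.

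The 2 pairs of single libraries were compared without p-values by the log2 ratio of CPM with a pseudocount of 1 CPM, over genes with at least 50 CPM in at least 1 library. Intervals of single genes are for the ratio without pseudocount. The median of each list was ranked among 10000 random lists matched on mean expression. The replicate pair at 5 ng served as a yardstick. For the 24 primers, a chi-square test of reads against a common share was run on genes with at least 120 reads in total. Coefficients of variation were computed over genes with a mean of at least 100 CPM.

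Named genes followed a rule. In the gradient these were, per contrast, up to 10 higher and 10 lower genes past the threshold with the largest change and a mean of at least 50 CPM. In the pairs they were the 10 highest and 10 lowest ratios. In the panel they were the 10 largest coefficients of variation and the 5 most abundant genes. In lists they were the 3 members with the highest mean and the one with the largest change, and deleted and rRNA genes were taken by name. The groups, tests, gene lists, naming rule and most alternatives were chosen before the data were examined.

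The alternatives were DESeq2, its size factors in edgeR, total counts, no filter or a mean of at least 10 CPM, rRNA kept, a test beyond 2-fold, thinning of each library to 3868 reads (gradient) or to the smallest library (pairs and panel), other pseudocounts, Spearman correlation, a replicate block, fewer inputs and leaving out each library. On simulated data with 50 genes changed 16-fold, edgeR recovered 36 at 1 ng, 33 at 100 pg, 5 at 10 pg, 0 at 1 pg and 1 at 100 fg, with 0 to 1 false calls. With 50 genes changed 2-fold it recovered 0 at every input. All simulated libraries followed the 5 ng shares, with 1 input changed at a time and without the genes that lead the lowest real inputs. The few false calls therefore do not carry over to the calls at 1 pg and 100 fg. The chi-square test called 0 of 3449 simulated genes when none changed, but 51 of 3264 unchanged genes when 200 others changed, since shares are relative. Of 2000 random lists without a shift, 6.25% fell outside the 95% range. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.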

Results

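RNA of Escherichia coli BW25113, a K-12 laboratory strain that carries deletions of araBAD, rhaBAD and lacZ, was sequenced in 40 libraries from cells in exponential growth in M63B1 minimal medium. miniBac-seq is a library method meant for very small amounts of bacterial RNA. The libraries form 4 comparisons. For rRNA depletion, 1 library was made after a commercial depletion and 1 after a customized one. To compare library methods, 1 library was made with miniBac-seq and 1 with the TruSeq kit, a standard RNA-seq kit. A gradient of total RNA held 2 libraries at each of 6 inputs between 5 ng and 100 fg. By their labels the 5 ng libraries also belong to another figure of the study, so contrasts against them may hold more than the input. A panel held 24 libraries, each with its own barcoded reverse transcription (RT) primer. The depletion pair held 3845090 (commercial) and 4357368 (customized) counted reads, and the method pair 6355497 (miniBac-seq) and 8153770 (TruSeq). In the gradient, totals of replicates 1 and 2 were 2190276 and 3059495 at 5 ng, 1598780 and 1991174 at 1 ng, and 120870 and 193706 at 100 pg. Below these they were 30049 and 47053 at 10 pg, 19488 and 19324 at 1 pg, and 16427 and 26494 at 100 fg. The primer libraries held 594983 to 2756378. The labels do not say whether libraries of one input came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Intervals and limits from counts cover counting error only.

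Ribosomal RNA, which makes up most bacterial RNA before depletion, took 0.0161% of the reads after commercial depletion (95% Wilson interval 0.0149 to 0.0174%) and 0.00186% after customized depletion (0.00150 to 0.00231%, 81 reads). The share was 0.0537% in the miniBac-seq library of the method pair (0.0519 to 0.0555%) and 0.707% in the TruSeq library (0.702 to 0.713%). It ranged from 0.458 to 0.966% over the 24 primer libraries. In the gradient it was 0.231 and 0.136% at 5 ng, 0.963 and 0.748% at 1 ng, and 8.65 and 6.29% at 100 pg. At the lower inputs it was 45.0 and 39.4% at 10 pg, 74.7 and 63.6% at 1 pg, and 76.5 and 74.8% at 100 fg. The number of rRNA reads from 1 ng down to 100 fg had a slope of -0.0109 in log10 reads per 10-fold of input (10 libraries), against 0.646 for the other reads. Over all 12 libraries, log10 rRNA reads and log10 input had r = -0.624 (permutation p = 0.022, adjusted 0.0264) and Spearman rho = -0.481 (permutation p = 0.12, adjusted 0.12), and r was -0.619 without the 2 libraries farthest from the median input.

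How far down the method reads the transcriptome was asked with the gradient. Of 4509 genes other than rRNA, 3799 ± 79.2 had at least 5 reads at 5 ng (mean ± SD, n = 2 at each input), 3513.5 ± 38.9 at 1 ng, 2040 ± 205 at 100 pg, 825 ± 160 at 10 pg, 198 ± 7.07 at 1 pg and 115.5 ± 0.707 at 100 fg. The number detected rose with log10 input over the 12 libraries (r = 0.967 and rho = 0.989, each with permutation p = 2e-05, the smallest that 100000 resamples can give two-sided, adjusted 3e-05 over 6 tests). Without the 2 libraries farthest from the median input r was 0.987, and it was 0.961 within replicate 1 and 0.974 within replicate 2. Depth fell with input: after each library was thinned to 3868 reads, the means were 177, 182, 179.5, 194, 125 and 95.5 genes from 5 ng to 100 fg. Log10 reads outside rRNA had r = 0.969 and rho = 0.975 with log10 input (permutation p = 2e-05, adjusted 3e-05), 0.987 without the same 2 libraries. Two-sided tests were used throughout.

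**Figure D1:**
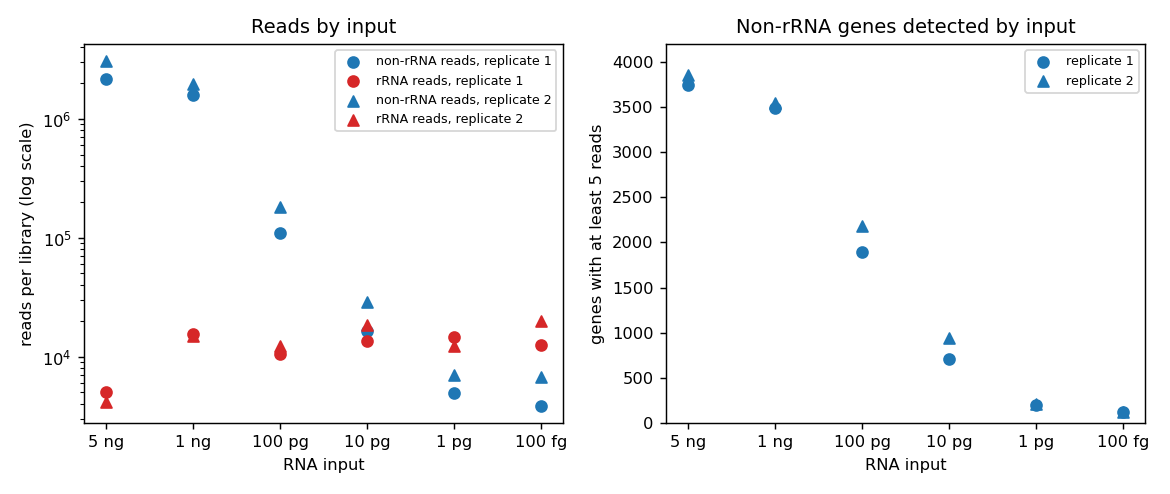
The left panel plots reads in rRNA and in all other genes per library, on a log axis, against total RNA input. The right panel plots the genes with at least 5 reads. The inputs stand in order at even steps. Points are single libraries; rRNA reads lie between 10458 and 19822 in each library from 1 ng to 100 fg, while the genes detected drop from 3799 (mean at 5 ng) to 115.5 (mean at 100 fg).

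Across genes, which are not independent replicates, the correlation of log2(CPM + 1) between the 2 libraries of an input was 0.980 at 5 ng, 0.951 at 1 ng, 0.777 at 100 pg, 0.512 at 10 pg, 0.293 at 1 pg and 0.196 at 100 fg. Genes with 0 reads in both libraries count toward these values. They were 2555 of 4509 at 10 pg, 3146 at 1 pg and 3591 at 100 fg. Of genes with at least 5 reads in either library, 92.7% (3656 of 3942) were found in both at 5 ng and 5.96% (13 of 218) at 100 fg, with 87.2, 64.8, 36.1 and 15.8% at the inputs between them. No pair agreed within counting error: chi-square per degree of freedom was 23.4, 20.2, 8.65, 12.8, 36.7 and 60.9 from 5 ng to 100 fg. The biological coefficient of variation fitted by edgeR to each input alone was 19.5, 20.8, 46.0, 121, 153 and 199%.

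At 1 ng, hcp (b0873) and hcr (b0872), which encode a hybrid cluster protein active on nitric oxide and its reductase, rose most against 5 ng. hcp was at 5534 ± 224 CPM against 7.13 ± 5.45 (mean ± SD, n = 2 each; log2 fold change 9.46, SE 1.23, edgeR quasi-likelihood adjusted p = 0.000461), and hcr at 1617 ± 417 against 5.50 ± 1.95 (8.00, SE 1.07, adjusted p = 0.000586). hmp, a nitric oxide dioxygenase, rose by 5.22, and ytfE, a protein of iron-sulfur cluster repair, by 5.74. bssR, a regulator of biofilm formation, rose by 6.76, and the outer membrane protein gene ompW by 5.97. The hydrogenase gene hyaC rose by 4.93, lsrC of autoinducer uptake by 4.87, yhiM by 4.64 and grcA, a spare part for pyruvate formate-lyase, by 4.59. The tryptophanase gene tnaA (b3708), at 70747 ± 8577 CPM at 5 ng, fell by 5.96 (SE 0.592, edgeR adjusted p = 4.56e-05) to 1255 ± 107, and the leader gene tnaC upstream of it fell by 5.46. pyrB (b4245), the catalytic subunit of aspartate carbamoyltransferase in pyrimidine synthesis, had 0 and 9 reads at 1 ng against 1395 ± 116 CPM at 5 ng (log2 fold change -9.21, SE 1.27, edgeR adjusted p = 0.00132).

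Its regulatory subunit pyrI fell by 7.44, and carB of carbamoyl phosphate synthesis by 5.37. carA had 0 and 3 reads at 1 ng against 369 and 646 at 5 ng. Of the putrescine degradation genes, puuA fell by 7.21 and puuE by 6.04, and puuB had 0 and 3 reads against 592 and 630. The histidine tRNA gene hisR fell by 6.43. In all 101 of 1637 genes differed at 1 ng (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 56 higher and 45 lower, and 311 had an unadjusted p under 0.05. The median log2 fold change of all genes tested was -0.32, and relative to it hcp rose by 9.78 and tnaA fell by 5.64. Split by other scalings, higher and lower genes were 165 and 461 with DESeq2 and 48 and 95 with its size factors in edgeR. Without 1 library the count was 4 (5 ng replicate 1), 6 (5 ng replicate 2), 8 and 9 (1 ng replicates 1 and 2) and 49 (either 100 pg library). It was 436 and 439 (10 pg replicates 1 and 2), 211 and 201 (1 pg replicates 1 and 2) and 227 and 225 (100 fg replicates 1 and 2). hcp, hcr, pyrB and tnaA passed in all 12 of these fits, and puuB, carA and puuE in the 6 that tested them. Without 5 ng replicate 1, edgeR adjusted p was 0.0839 for bssR, 0.133 for ompW and ytfE, 0.124 for hmp and 0.452 for grcA. Without 5 ng replicate 2 it was 0.419 for hyaC, 0.255 for yhiM, 0.416 for pyrI and puuA, 0.565 for tnaC and 0.508 for carB. Without 1 ng replicate 1 it was 0.805 for lsrC and 0.470 for hisR. With DESeq2, pyrB, puuB, carA, puuE and hisR had adjusted p between 0.0574 and 0.224.

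**Figure D2:**
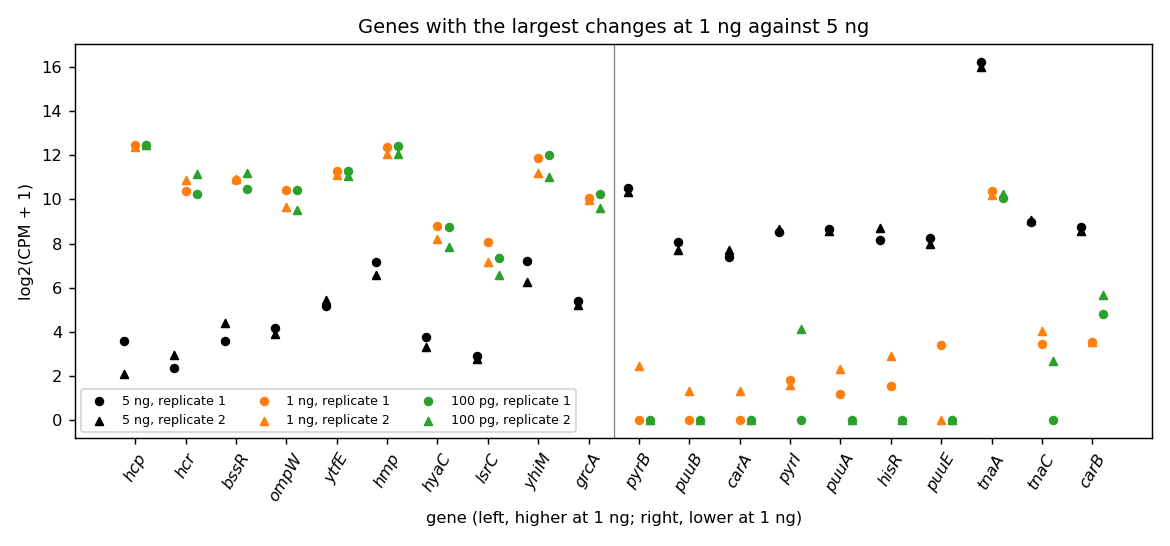
Log2(CPM + 1) of the 20 genes named at 1 ng (10 higher, 10 lower) is plotted for each replicate library of the 3 highest inputs. hcp lies near 5534 CPM at 1 ng and 5700 CPM at 100 pg against 7.13 CPM at 5 ng, and tnaA near 1255 and 1137 CPM against 70747 CPM.

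Among the gene lists fixed beforehand, genes of the general stress response under the sigma factor RpoS rose as a group at 1 ng. Of 30 members tested, 11 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 1.49 against -0.32 for all genes (limma camera, Benjamini-Hochberg adjusted p = 2.58e-09; adjusted p = 0.0472 with an estimated correlation). The DNA-binding protein gene dps was at 27856 ± 9269 CPM against 4139 ± 1567 (n = 2 each; log2 fold change 2.60, SE 0.561, edgeR adjusted p = 0.00941), and gadB, a glutamate decarboxylase of acid resistance, at 28254 ± 1662 against 5209 ± 159 (2.29, SE 0.467, adjusted p = 0.00737). hdeD, of the acid resistance island, rose by 3.94, and gadA by 2.05; gadA and gadB are near-identical copies whose reads the counting may have split. The other members past the threshold, named after their values were seen, were gadC, hdeA, hdeB, osmB, slp, sra and yjbJ. Without 1 ng replicate 2, edgeR adjusted p was 0.558 for gadB, 0.630 for dps and 0.769 for gadA, and without 5 ng replicate 1 it was 0.325 for hdeD.

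Glycolysis and tricarboxylic acid cycle genes fell as a group at 1 ng: 6 of 30 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -1.14 (limma camera adjusted p = 1.80e-05; adjusted p = 0.0656 with an estimated correlation). The 6, named after their values were seen, belong to the tricarboxylic acid cycle or its dehydrogenases: acnB (aconitase, -3.93, SE 0.971, edgeR adjusted p = 0.0224), fumA, fumC, lpd, sdhA and sdhC. acnB had adjusted p = 0.442 in edgeR without 1 ng replicate 1, and the aconitase gene acnA was at -0.27. Of 9 ATP synthase genes 0 passed over all genes and 5 fell adjusted over the list alone, with a median of -2.09 and atpD at 775 ± 86.0 CPM against 2987 ± 94.3 (limma camera adjusted p = 0.000224; adjusted p = 0.0472 with an estimated correlation). Of 5 tRNA genes 4 fell (hisR, argY, leuT, thrT; 5 adjusted over the list alone), with a median of -3.04 (limma camera adjusted p = 0.000255; adjusted p = 0.0656 with an estimated correlation).

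The other lists did not pass at 1 ng. Of 49 ribosomal protein genes 0 changed on either adjustment (median -0.16, limma camera adjusted p = 0.963), with rpsA at 3096 ± 910 CPM against 3792 ± 775. Of 40 amino acid biosynthesis genes gltB, for glutamate synthase, fell (1 higher and 2 lower adjusted over the list alone; median -0.57, camera adjusted p = 0.433). Of 17 heat shock genes 0 changed on either adjustment (median 0.11, camera adjusted p = 0.239), with dnaK at 8965 ± 594 CPM against 5577 ± 1545. Of 19 envelope genes ompW, ompX and osmB rose and the outer membrane protease gene ompT fell (3 and 1 adjusted over the list alone; median 0.13, camera adjusted p = 0.249). Of 5 small RNA genes rnpB, the RNA of ribonuclease P, fell by 2.76 (1 higher and 1 lower adjusted over the list alone; median -0.20, camera adjusted p = 0.911). In edgeR, rnpB had adjusted p = 0.642 without 5 ng replicate 2. The lists of flagella (2 tested), leader peptides (1 tested, tnaC) and deleted genes (1 tested, lacZ, edgeR adjusted p = 0.358) were too small for the group test, and 0 of the flagellar genes changed.

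At 100 pg the levels of these genes lay near those at 1 ng: hcp was at 5700 ± 59.7 CPM (n = 2), hcr at 1738 ± 729, gadB at 27629 ± 1493, dps at 26291 ± 9720 and tnaA at 1137 ± 83.2. Against 5 ng, hcp rose by 9.23 (SE 1.22, edgeR adjusted p = 0.000566), hcr by 7.81, bssR by 6.47, ompW by 5.68 and ytfE by 5.46. hmp rose by 4.97, hyaB by 4.55, hyaC by 4.48, yhiM by 4.40 and hyaE by 4.39. tnaA fell by 6.38 (SE 0.604, adjusted p = 2.36e-05). With 0 reads in both libraries, pyrB was at least 136-fold lower, puuA 38.1-fold, hisR 34.2-fold, puuE 26.8-fold, puuB 23.2-fold and carA 18.5-fold, where 0 is taken as 3 reads over both libraries. tnaC had 0 and 1 reads, ompT 2 and 0, and pyrI 0 and 3, against 1109 and 1640, 1575 and 1737, and 794 and 1218 at 5 ng. In all, 91 genes differed, 39 higher and 52 lower (368 at an unadjusted p under 0.05), 7 of the lower ones with 0 reads in both libraries, and the median of all genes was -0.50. Against 1 ng, a comparison added after the data were seen, edgeR called 0 genes (25 at an unadjusted p under 0.05), and a fit of these 2 inputs alone also called 0 (114 unadjusted); 0 calls do not show that the inputs gave the same levels.

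Higher and lower genes at 100 pg against 5 ng were 142 and 452 with DESeq2, 41 and 101 with its size factors in edgeR, 60 and 40 by total counts and 71 and 43 with rRNA kept. They were 103 and 54 with a mean of at least 10 CPM. Without 1 library the count of 91 was 4 (5 ng replicate 1), 6 (5 ng replicate 2), 29 (either 1 ng library) and 8 and 10 (100 pg replicates 1 and 2). It was 447 and 471 (10 pg replicates 1 and 2), 178 and 202 (1 pg replicates 1 and 2) and 186 and 188 (100 fg replicates 1 and 2). hcp, hcr and tnaA passed in all 12, and hyaE, puuE, puuB and carA in the 6 fits that tested them. Without 5 ng replicate 1, edgeR adjusted p was 0.114 for bssR, 0.123 for ompW, 0.122 for ytfE, hmp and hisR, and 0.257 for hyaB. Without 5 ng replicate 2 it was 0.460 for hyaC, 0.259 for yhiM, 0.368 for puuA, 0.442 for tnaC, 0.339 for ompT and 0.771 for pyrI. Without 100 pg replicate 2 it was 0.0580 for pyrB. In edgeR, gadB had adjusted p = 0.656 and dps 0.701 without 5 ng replicate 1. With DESeq2, adjusted p was 0.0949 for pyrB, 0.123 for puuE, 0.224 for puuB and 0.249 for carA. Of the RpoS list 8 rose and 0 fell at 100 pg (13 and 0 adjusted over the list alone; limma camera adjusted p = 2.58e-09, adjusted p = 0.0472 with an estimated correlation). Of the glycolysis and tricarboxylic acid cycle list 7 fell (11 over the list alone; camera adjusted p = 6.36e-06, adjusted p = 0.0653 with an estimated correlation), of ATP synthase 2 fell, atpE and atpH (7 over the list alone; 0.000336, adjusted p = 0.0472 with an estimated correlation), and of the tRNA genes 3 fell (5 over the list alone; 0.00111, adjusted p = 0.0812 with an estimated correlation). In edgeR, atpH had adjusted p = 0.978 without 5 ng replicate 2. The contrasts share the 5 ng libraries and are not independent of each other.

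At 10 pg, hcp (41 and 143 reads, 3748 ± 1791 CPM, n = 2) and hcr (24 and 16 reads) still lay above 5 ng, by 8.08 (SE 1.17, edgeR adjusted p = 0.00172) and 6.58 (SE 1.02, adjusted p = 0.0029). ssrA, the transfer-messenger RNA that rescues stalled ribosomes, had 3 and 18 reads against 3 and 1 at 5 ng. Other genes named as higher rested on few reads: ycdU 0 and 7, yehD 3 and 5, yehL 5 and 3, fryC 9 and 0, hiuH 0 and 16, atoE 5 and 2, and ydhY 10 and 0. The lower genes named had 0 reads in both libraries. pyrB was at least 20.9-fold lower, mglB of galactose uptake 16.6-fold, glaH 14.2-fold and cyoA and cyoC of cytochrome bo oxidase 13.0-fold and 10.4-fold. The glycerol 3-phosphate transporter gene glpT was at least 11.1-fold lower, gabP 10.4-fold, the carbonic anhydrase gene can 9.87-fold, ompT 9.68-fold and ptsP 8.67-fold. In all 348 genes differed (46 higher, 302 lower, and 594 unadjusted), 146 of the lower ones at 0 in both libraries and 9 of the higher ones with reads in 1 library. The median of all genes was -1.10. Against 1 ng, a comparison added after the data were seen, edgeR called 2 genes (391 unadjusted). A fit of these 2 inputs alone called 0 (378 unadjusted). Such low counts do not show that the inputs gave the same levels.

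Higher and lower genes at 10 pg were 165 and 502 with DESeq2, 67 and 59 by total counts and 68 and 154 with rRNA kept. The 348 became 29 and 7 without 5 ng replicates 1 and 2, 120 and 118 without 1 ng replicates 1 and 2, 173 and 179 without 100 pg replicates 1 and 2, 692 without 10 pg replicate 1 and 747 without 1 pg replicate 2. Without 5 ng replicate 2, ssrA had edgeR adjusted p = 0.116, and the 10 lower genes named had 0.114 (mglB) to 0.250 (can). ycdU and hiuH were not higher without 10 pg replicate 2, nor fryC and ydhY without replicate 1. With DESeq2, yehD and pyrB had adjusted p = 0.0589 and 0.213. Of the glycolysis and tricarboxylic acid cycle list 16 of 30 fell, mdh and acnB among them (21 adjusted over the list alone; limma camera adjusted p = 7.49e-06, adjusted p = 0.0653 with an estimated correlation). The RpoS list was shifted up (camera adjusted p = 7.11e-05, adjusted p = 0.0656 with an estimated correlation), with gadC, hdeA, hdeB, hdeD and osmB higher and otsB and ygaM lower on both adjustments. In edgeR, mdh had adjusted p = 0.450 and otsB 0.143 without 5 ng replicate 2. ATP synthase (5 of 9 lower; 6 over the list alone), ribosomal proteins (11 of 49 lower on both adjustments) and tRNA (4 of 5 lower on both) had camera adjusted p = 0.0116, 0.0126 and 0.0262, and adjusted p = 0.0741, 0.198 and 0.203 with an estimated correlation; by total counts the ribosomal protein list had adjusted p = 0.0843.

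At 1 pg the genes lower with 0 reads in both libraries included narG of nitrate reductase (at least 10.5-fold lower), the ribosomal protein gene rpsN (8.62-fold), gabT (8.26-fold) and pheT of phenylalanyl-tRNA synthetase (8.15-fold). They also included the transketolase gene tktA (7.95-fold), priB (6.49-fold), pepN (6.13-fold), tdh (6.09-fold), glmS (5.79-fold) and pyrB (5.56-fold). Genes named as higher had ycdU 0 and 9 reads, hiuH 0 and 13, fliR 10 and 0, yqiI 5 and 0, lacZ 6 and 0, ydiN and hokA 2 and 0 each, pdeH 1 and 9, yfcC 1 and 12, and ssrA 4 and 4. In all 247 genes differed (edgeR; 40 higher, 207 lower; 623 unadjusted), 96 of the lower ones at 0 in both libraries and 21 of the higher ones with reads in 1 library. The median of all genes was -2.35, and 203 of the lower genes fell by more than that. Of the glycolysis and tricarboxylic acid cycle list 20 of 30 fell (27 adjusted over the list alone; limma camera adjusted p = 2.18e-08, adjusted p = 0.0472 with an estimated correlation) and of ribosomal proteins 21 of 49 (36 over the list alone; 2.35e-06, adjusted p = 0.0542 with an estimated correlation). ATP synthase (5 of 9 lower, 8 over the list alone) and the envelope list (7 lower and ompW higher; 11 and 1 over the list alone) had camera adjusted p = 0.00518 and 0.0342, and adjusted p = 0.0656 and 0.198 with an estimated correlation; by total counts the envelope list had adjusted p = 0.0662. Of the RpoS list 5 fell (6 lower and 1 higher over the list alone; camera adjusted p = 0.764). Higher and lower genes were 219 and 142 with DESeq2, 49 and 37 with its size factors in edgeR, 48 and 62 by total counts and 52 and 63 with rRNA kept. The 247 became 30 and 15 without 5 ng replicates 1 and 2, 119 and 124 without 1 ng replicates 1 and 2, 581 and 578 without 10 pg replicates 1 and 2, and 116 and 122 without 1 pg replicates 1 and 2. In edgeR, pyrB had adjusted p = 0.138, glmS 0.0726, pepN and tdh 0.0611 and ssrA 0.0626 without 5 ng replicate 2. Without 1 pg replicate 1 it was 0.0526 for gabT and 0.0571 for priB, and fliR, yqiI, lacZ, ydiN and hokA were not higher. Without 1 pg replicate 2 it was 0.446 for pdeH and 0.426 for yfcC, and ycdU and hiuH were not higher. With DESeq2, ydiN, hokA and pyrB had adjusted p = 0.0566, 0.0737 and 0.462.

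At 100 fg tnaA, the gene with the most reads at 5 ng, had 0 reads in both libraries and was at least 249-fold lower. The other lower genes named, also at 0 in both libraries, included mdh (malate dehydrogenase, at least 34.6-fold lower), sucC (20.2-fold), lpd (19.5-fold), icd (isocitrate dehydrogenase, 18.3-fold) and sdhA (12.4-fold). They also included fbaA (aldolase, 11.6-fold), acs (acetyl-CoA synthetase, 16.1-fold), dppA of dipeptide uptake (24.0-fold) and rplP (10.7-fold). Genes named as higher had ycdU 0 and 12 reads, hokA 8 and 0, ydiN 4 and 1, hiuH 0 and 17, bglB 1 and 24, ydhY 14 and 0, yqiI 9 and 0, wzxC 0 and 23, yfcC 4 and 16, and ssrA 4 and 4. In all 394 genes differed (edgeR; 61 higher, 333 lower; 691 unadjusted), 241 of the lower ones at 0 in both libraries and 38 of the higher ones with reads in 1 library. The median of all genes was -8.66, and only the 241 at 0 fell by more than that. Of the glycolysis and tricarboxylic acid cycle list 25 of 30 fell (28 adjusted over the list alone; limma camera adjusted p = 4.81e-09) and of ribosomal proteins 30 of 49 (44 over the list alone; 5.42e-07), both with adjusted p = 0.0472 with an estimated correlation. Of the RpoS list 19 fell (22 over the list alone), of the envelope list 11 (12), of ATP synthase 6 (6) and of heat shock genes 7 (10), with camera adjusted p = 0.000831, 0.00523, 0.0116 and 0.0126, and adjusted p = 0.0945, 0.0967, 0.0741 and 0.156 with an estimated correlation. Genes abundant at 5 ng can fall further before they reach 0 reads. The list tests at 1 pg and 100 fg therefore cannot part a change of a list from its starting abundance. The folds given for genes at 0 take 0 as 3 reads over both libraries together, as if both held 1 level. In a single library, a count of 0 at 100 fg allows up to 776 CPM in replicate 1 and 450 CPM in replicate 2, so a bound from 1 library alone would be weaker. The folds are also of shares of all reads outside rRNA. Genes with at least 30 reads at 100 fg took 54.9% and 73.1% of these at 100 fg and 40.0% and 55.5% at 1 pg (replicates 1 and 2). Over the remaining reads the bounds at both inputs would be lower. Part of the fold of tnaA was present at 1 ng, where it was at 1255 CPM. Higher and lower genes were 248 and 123 with DESeq2, 88 and 69 with its size factors in edgeR and 68 and 183 by total counts. The median of all genes was -0.88 with DESeq2 and -8.80 with its size factors in edgeR. Those size factors rest on the 58 genes with reads in all 12 libraries. The 394 became 139 without 5 ng replicate 1, 238 without either 1 ng library, 640 and 637 without 10 pg replicates 1 and 2, and 1093 without 1 pg replicate 1. The 10 lower genes named passed in all 12 of these fits. In edgeR, ydiN had adjusted p = 0.0764 without 5 ng replicate 1. Without 100 fg replicate 2 it was 0.639 for bglB, and wzxC, ycdU and hiuH were not higher, nor were ydhY and yqiI without replicate 1.

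The slope on log10 input over the 12 libraries passed for 836 of 1637 genes (edgeR quasi-likelihood, Benjamini-Hochberg; 966 unadjusted), 670 rising with input and 166 falling. The split was 257 and 233 with DESeq2, 209 falling of 485 with its size factors in edgeR, and 239 and 183 by total counts. It was 118 rising and 143 falling without the 5 ng libraries, a fit added after the data were seen, 8 and 57 thinned to the smallest library, and 13 and 14 beyond 2-fold. The count was 550 and 341 without 5 ng replicates 1 and 2, 537 and 535 without 1 ng replicates 1 and 2, and 504 and 510 without 100 fg replicates 1 and 2.

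A set of genes had many reads at the lowest inputs, mostly in 1 replicate number. barA, a sensor kinase gene, had 639, 788, 702, 757 and 921 reads in replicate 1 from 1 ng to 100 fg, and 137, 34, 16, 15 and 109 in replicate 2. mrcA, for a penicillin-binding protein, had 738, 862, 876, 983 and 1243 reads in replicate 2, and 80, 8, 0, 0 and 11 in replicate 1. yfhL had 324 to 396 reads in replicate 1, and the ammonium transporter gene amtB 341 to 578 in replicate 2. Genes with at least 30 reads at 100 fg numbered 14 in replicate 1 and 23 in replicate 2. They were 36 in all, with barA in both, and the limit was set after the values were seen. Of the reads outside rRNA they took 54.9% and 73.1% at 100 fg, and 40.0% and 55.5% at 1 pg. They took 10.6% and 12.3% at 10 pg, 1.81% and 2.53% at 100 pg, and 0.176% and 0.948% at 1 ng. At 5 ng they took 0.142% and 1.03%, against 0.127% and 0.951% in the other replicate number.

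**Figure D3:**
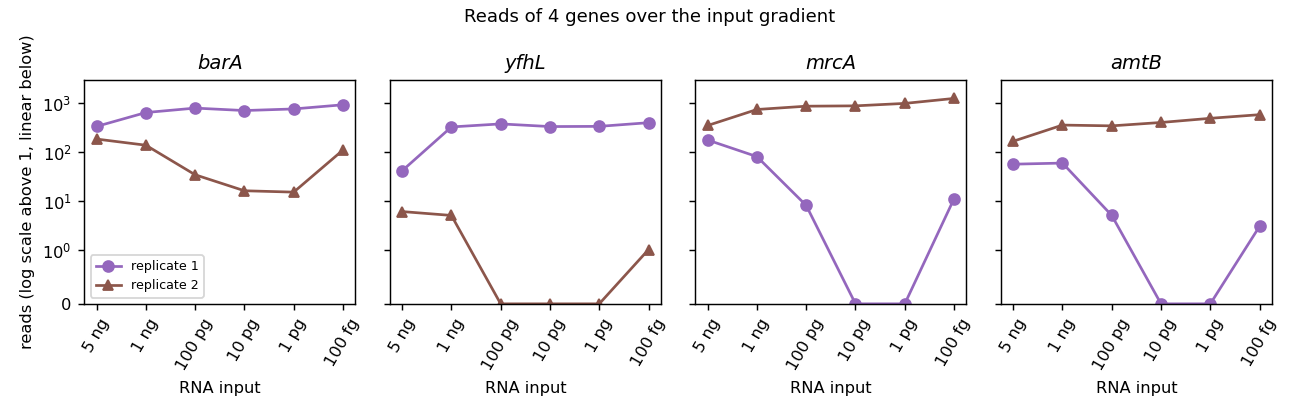
Reads of barA, yfhL, mrcA and amtB, on an axis that is log above 1 and linear below, are plotted against total RNA input for each replicate library. The inputs stand in order at even steps. From 1 ng to 100 fg barA stays between 639 and 921 reads in replicate 1, and mrcA between 738 and 1243 in replicate 2.

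After customized depletion, ssrA (b2621) had 18 reads against 64159 after commercial depletion, a log2 ratio of CPM of -11.67 with a pseudocount of 1 CPM. Each depletion has 1 library, so no difference has a replicate check and intervals compare these libraries only. csrB, a small RNA that binds the carbon storage regulator CsrA, had 18307 reads against 1313 (log2 ratio 3.62, counting interval 3.54 to 3.70). The stress-linked genes pspE and yjbJ were higher by 2.32 and 2.22, followed by ydiZ (1.97), yraR (1.90), yaiA (1.89), rpmF (1.79), ecnB (1.76), bolA (1.67) and hupB (1.64). Besides ssrA, the lowest were ybaA (-1.38), tff (-1.11), yrbG (-1.03), yciO (-1.02), then atpI and sulA, rpsQ (-0.96), ftsW (-0.95) and melB (-0.95).

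Across genes the depletion pair had r = 0.985, and 97.1% of genes with at least 50 CPM (1757 of 1810; 95% Wilson interval 96.2 to 97.8%) lay within 2-fold, with 47 higher and 6 lower. The pair of 5 ng libraries gave r = 0.980 and 1896 of 1945 genes within 2-fold (96.7 to 98.1%), with 34 higher and 15 lower in replicate 2. The small RNA list (9 members) had a median of 1.03, above 100% of 10000 random lists of its size matched on expression (95% range -0.35 to 0.33), although ssrA in it went the other way. The random lists were not matched on length, and short genes were higher in general: with tRNA left out, the median was 0.32 for 27 genes under 200 nt (6 over 2-fold higher, 1 lower) and 0.42 for 83 of 200 to 300 nt (17 higher, 0 lower), and length and ratio had Spearman rho = -0.169 across 1808 genes. The other lists lay inside their 95% random ranges: tRNA 0.18 (31 members, percentile 96.6), tRNA inside rRNA operons -0.10 (6, 43.7), leader peptides 0.31 (5 members, percentile 91.5), heat shock 0.07 (18, 83.9), ATP synthase 0.09 (9, 79.4), ribosomal proteins 0.02 (54, 78.6), flagella 0.01 (15, 62.3), glycolysis and tricarboxylic acid cycle -0.01 (31, 57.8), RpoS -0.04 (30, 45.3), amino acid biosynthesis -0.06 (79, 39.6) and envelope -0.10 (23, 24.0). By TMM scaling, which adds 0.03, glycolysis became 0.02.

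The lowest genes in the miniBac-seq library against TruSeq were mostly RNAs that are short or not translated. ssrA had 19 reads against 95328 (log2 ratio -11.53), the iron-stress small RNA ryhB 3 against 1989 (-9.02 without pseudocount, counting interval -11.30 to -7.47), and lpp, for the abundant outer membrane lipoprotein, 134 against 29366 (-7.36). Then came rmf, for the ribosome hibernation factor (-6.05), the small RNA glmZ (3 against 549 reads, -7.17 without pseudocount, interval -9.45 to -5.61), the leader peptide genes ilvL (-5.10), leuL (-4.87) and mgtL (-4.35), and the tRNA genes gltU (-4.36) and metY (-4.26). The highest were the tRNA genes metU (335 against 1 read, 8.74 without pseudocount, interval 6.25 to 14.05) and leuT (2.92), then rspB (2.59), yahO (2.59), yjjZ (2.41), yciO (2.35), yhdE (2.30), priB for a replication protein (2.27), frmR (2.20) and birA. metU and metY belong to families of near-identical copies whose reads may have been split between them. Each method has 1 library, so no difference has a replicate check.

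Medians of tRNA (48 members, -1.05), tRNA inside rRNA operons (7, -3.59), small RNAs (17, -2.86) and leader peptides (10, -3.16) lay below all of 10000 matched random lists. Over 2-fold lower were 24 of the 48 tRNA genes, with 8 over 2-fold higher, and 15 of the 17 small RNAs and 9 of the 10 leader peptides, with 0 higher. RpoS genes had a median of 0.28 (30 members, percentile 99.1) and glycolysis and tricarboxylic acid cycle genes -0.25 (30, percentile 1.91), while ribosomal proteins (54, -0.09, percentile 10.9), amino acid biosynthesis (82, -0.09, 18.2), flagella (27, -0.32, 30.9), ATP synthase (9, -0.09, 33.3), heat shock (18, -0.07, 40.5; 0.00 by TMM scaling, which adds 0.08) and envelope genes (23, 0.18, 84.4) lay inside the random range. By length, with tRNA left out, the median was -1.57 for 33 genes under 200 nt (20 over 2-fold lower, 6 higher), -0.68 for 76 of 200 to 300 nt (30 lower, 13 higher), and between -0.08 and 0.03 for each longer class. Across genes r was 0.948, and 84.1% of genes with at least 50 CPM (1743 of 2073; 82.4 to 85.6%) lay within 2-fold, with 142 higher and 188 lower.

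**Figure D4:**
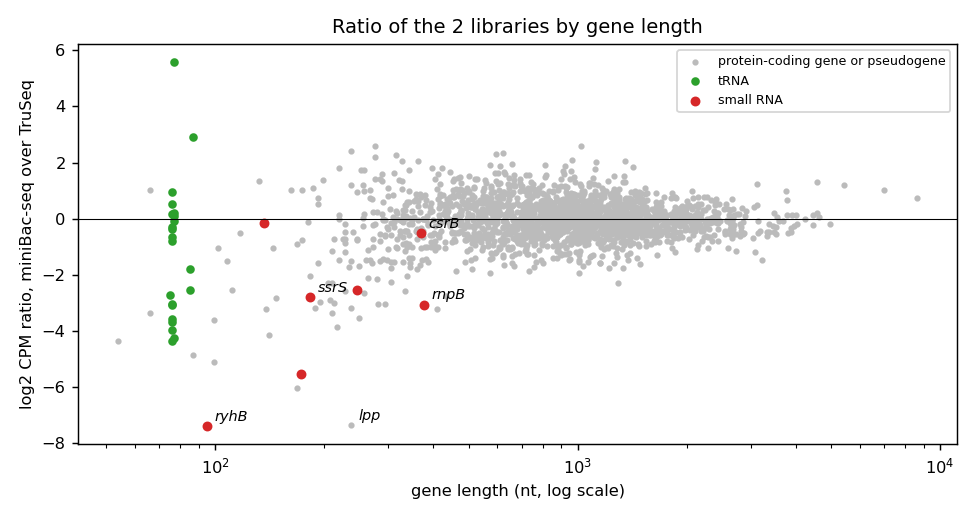
The log2 ratio of CPM (miniBac-seq over TruSeq) is plotted against gene length in nucleotides, a log axis, with 1 point per protein-coding gene, pseudogene, tRNA or small RNA. Genes under 200 nt other than tRNA have a median of -1.57, and longer classes from 300 nt on lie near 0. ssrA, at -11.53, is filed under none of these classes and has no point.

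The 24 RT primers asked whether a barcode in the primer changes what is counted. Of the 5 most abundant genes, tdcE, a 2-ketobutyrate formate-lyase gene, was at 10156 ± 1040 CPM (SD, n = 24; coefficient of variation 10.2%), and ompC, an outer membrane porin gene, at 13009 ± 1969 (15.1%). tufA, 1 of 2 near-identical copies of the elongation factor Tu gene, was at 15433 ± 2467 (16.0%), gapA of glycolysis at 15762 ± 3532 (22.4%) and fusA, for elongation factor G, at 12421 ± 4066 (32.7%, or 10.9% without primer 8). Single primers carried large amounts of single genes: hisR was at 6040 CPM with primer 3 and at most 261 with any other (coefficient of variation 315%, 51.9% without primer 3), and ilvE, a branched-chain aminotransferase gene, at 1770 CPM with primer 8 and at most 127 elsewhere (255%, 33.6% without primer 8). ybcH (115%), ygiN (103%), yfcZ (101%), the tRNA gene metW (99.0%), the small RNA gcvB (91.1%), fdnI of formate dehydrogenase (86.4%), rlpA (85.9%) and the tRNA gene tyrU (83.5%) followed.

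Over 1232 genes with a mean of at least 100 CPM the median coefficient of variation was 20.8% (quartiles 16.8 and 26.9%), where counting alone gives a median of 5.27%; 43 genes exceeded 50% and 5 exceeded 100%. Reads of 3449 of 3454 genes (99.9%) varied beyond a common share (chi-square test on reads, Benjamini-Hochberg), with a median chi-square per degree of freedom of 6.76, and the common biological coefficient of variation was 35.8%. Pairwise r between the primer libraries had a median of 0.952 (0.909 to 0.971). By list, the median coefficient of variation was 46.9% for small RNAs (4 genes), 32.3% for tRNA (21), 31.5% for tRNA inside rRNA operons (2), 30.5% for leader peptides (2), 26.9% for ATP synthase (9), and 26.8% for ribosomal proteins (54). It was 23.7% for flagella (1), 22.7% for RpoS (3), 20.6% for amino acid biosynthesis (23), 20.1% for the envelope (19), 17.2% for glycolysis and the tricarboxylic acid cycle (29) and 16.1% for heat shock (15). Each primer has 1 library, so a primer cannot be separated from its library.

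**Figure D5:**
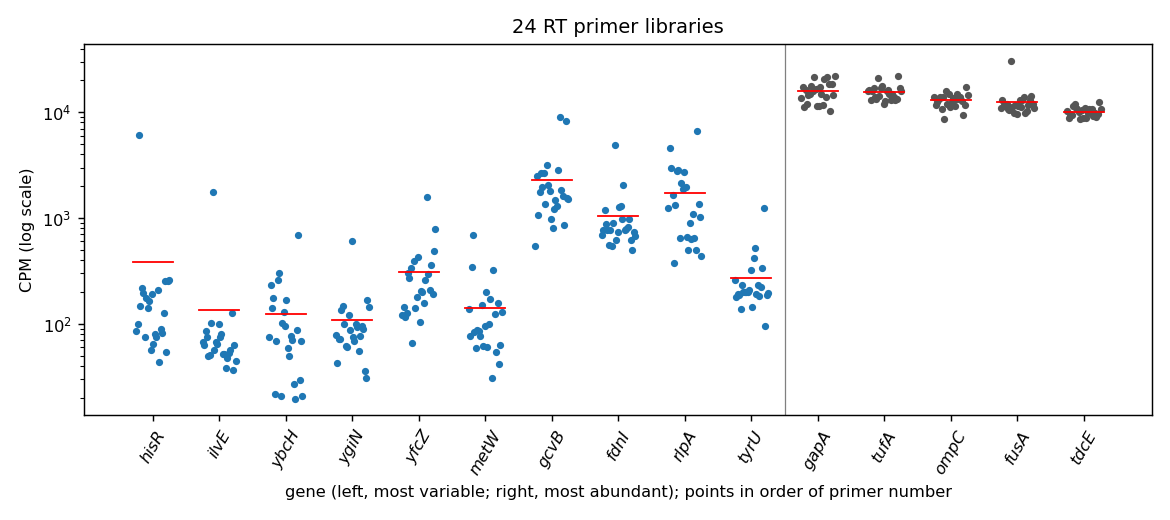
CPM of the 10 genes with the highest coefficient of variation and of the 5 most abundant genes is plotted for each of the 24 primers on a log axis, with the mean as a red line. hisR stands at 6040 CPM with primer 3, ilvE at 1770 CPM with primer 8 and fusA at 30597 CPM with primer 8.

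The genes deleted from the strain had 136 reads over the 40 libraries, at most 15 in one library. lacZ, which passed as higher in edgeR at 10 pg (5 and 2 reads, against 5 and 3 at 5 ng) and at 1 pg (6 and 0), had 70 of them, araB 19, rhaB 17, araA 9, rhaA 9, araD 6 and rhaD 6. In edgeR, lacZ at 10 pg had adjusted p = 0.502 without 5 ng replicate 2.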

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

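The comparisons against 1 ng, the fits of 2 inputs alone, the fits without the 1 pg and 100 fg libraries, the slope without the 5 ng libraries and the analyses without the 36 background genes were chosen after the data were seen. Of the values under alternatives for the main results, 192 stayed within their tolerance and 159 moved. For single genes and lists 2807 stayed, 293 kept their direction but missed the threshold, 55 moved and 36 reversed. Unless a reason is given, the cause was not tested.

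hcp, hcr and tnaA at 1 ng and 100 pg passed without any 1 library. The number of genes called did not hold. With DESeq2 it was 626 at 1 ng, 594 at 100 pg, 667 at 10 pg and 490 for the slope. With size factors of DESeq2 in edgeR it was 142 at 100 pg, 86 at 1 pg, 157 at 100 fg and 485 for the slope. By total counts it was 126 at 10 pg, 110 at 1 pg, 251 at 100 fg and 422 for the slope. With no filter on low counts, which tests more genes, it was 317 at 1 ng, 243 at 100 pg and 1440 for the slope. With a mean of at least 10 CPM, which tests 3024 genes, it was 206 at 1 ng, 157 at 100 pg and 1045 at 100 fg. With rRNA kept it was 222 at 10 pg and 115 at 1 pg. Beyond 2-fold, a stricter test, it was 61 at 1 ng, 49 at 100 pg, 213 at 10 pg and 27 for the slope. Thinned to the smallest library, which leaves few reads, it was 5 at 1 ng, 4 at 100 pg, 0 at 10 pg, 4 at 1 pg, 5 at 100 fg and 65 for the slope.

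Without the 1 pg and 100 fg libraries in the fit, 351 genes passed at 1 ng and 252 at 100 pg. Without background genes it was 209 at 1 ng, 183 at 100 pg and 793 at 100 fg. A fit of the 2 compared inputs alone gave 1201 at 1 ng, 426 at 100 pg, 33 at 10 pg, 401 at 1 pg and 1169 at 100 fg. Against 1 ng in place of 5 ng, edgeR called 0 at 100 pg (25 at an unadjusted p under 0.05) and 2 at 10 pg. Against 1 ng with the 2 inputs fitted alone, edgeR called 0 at 100 pg (114 unadjusted), 0 at 10 pg (378 unadjusted) and 947 at 100 fg; DESeq2 was not run for these. The slope passed for 244 genes without the 100 fg libraries, 251 without the 100 fg and 1 pg libraries, and 261 without the 5 ng libraries.

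Leaving out 1 library at a time gave 4 to 439 genes at 1 ng, 4 to 471 at 100 pg, 7 to 747 at 10 pg, 15 to 581 at 1 pg, 139 to 1093 at 100 fg and 341 to 1232 for the slope. This leaves an input with 1 library, which is assumed to vary like the other inputs, and it changes how many genes pass the filter. With an estimated correlation, 2 lists passed at 1 ng, 2 at 100 pg, 0 at 10 pg, 1 at 1 pg and 2 at 100 fg, against 4, 4, 5, 4 and 6.

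As a check on pairing, replicate 1 minus replicate 2 was correlated between inputs over 1864 genes: r had a median of 0.21 over 15 pairs of inputs (0.04 to 0.42), 12 of them over 0.1. Over 392 abundant genes it was 0.79 between 5 ng and 1 ng and 0.78 between 1 ng and 100 pg. Of 12 libraries, 11 correlated best with a library of the same replicate number at another input. The main fit leaves this tie by replicate number out. With the replicate number as a block, 131 genes passed at 1 ng, 131 at 100 pg, 374 at 10 pg, 280 at 1 pg and 397 at 100 fg, and 828 for the slope.

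Against 1 ng, the log2 fold change at 100 pg was -0.29 for bssR, -0.23 for hcp, -0.19 for hcr, -0.25 for hmp, -0.0182 for hyaB, -0.45 for hyaC, -0.29 for ompW, 1.76 for pyrI, -0.24 for yhiM and -0.28 for ytfE. With these 2 inputs fitted alone it was -0.0304 for bssR, -0.0223 for hmp, -0.24 for hyaC, -0.0842 for ompW, -0.0410 for yhiM and -0.0488 for ytfE. At 10 pg it was -1.38 for hcp and -1.41 for hcr, or -0.93 and -1.15 fitted alone. The change of reference accounts for these signs. Some named genes with reads in 1 library of an input took the other sign without it, or a log2 fold change of 0. Over fits leaving out 1 library, the log2 fold change at 10 pg ranged from -2.89 to 8.25 for fryC and -3.55 to 7.38 for ydhY (lowest without 10 pg replicate 1), and from -3.19 to 7.73 for hiuH and 0 to 9.64 for ycdU (lowest without replicate 2). At 1 pg it ranged from -3.14 to 10.18 for fliR, -3.47 to 8.21 for lacZ, -2.86 to 8.43 for yqiI and 0 to 10.08 for hokA and ydiN (lowest without 1 pg replicate 1), and from -3.20 to 9.85 for hiuH and 0 to 12.40 for ycdU (lowest without replicate 2). At 100 fg it ranged from -3.43 to 9.77 for ydhY and -2.85 to 9.98 for yqiI (lowest without 100 fg replicate 1), and from -4.85 to 8.19 for wzxC, -3.08 to 10.22 for hiuH and 0 to 12.47 for ycdU (lowest without replicate 2).

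Genes detected with at least 1 read were 4203, 3873, 2810.5, 1381, 853.5 and 530 from 5 ng to 100 fg, and with at least 10 reads 3505, 3175.5, 1532, 485, 81.5 and 55.5. Thinned they were 177, 182, 179.5, 194, 125 and 95.5. At equal depth the 4 highest inputs gave like counts, which cannot part depth from RNA amount, since reads outside rRNA rose with input (r = 0.969). Without background genes they were 178 at 1 pg and 93 at 100 fg. Single libraries ranged over 3743 to 3855, 3486 to 3541, 1895 to 2185, 712 to 938, 193 to 203 and 115 to 116.

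Replicate r with a pseudocount of 0.1 CPM was 0.961 at 5 ng, 0.908 at 1 ng, 0.719 at 100 pg and 0.484 at 10 pg. With 10 CPM it was 0.976 at 1 ng, 0.850 at 100 pg and 0.561 at 10 pg. Over genes with a mean of at least 10 CPM it was 0.531 at 100 pg, -0.0640 at 10 pg, -0.475 at 1 pg and -0.619 at 100 fg. At the lowest inputs this filter drops genes at 0 in both libraries and keeps genes with reads in only 1. Spearman's rho was 0.494 at 10 pg and 0.178 at 100 fg, and with rRNA kept r was 0.536 at 10 pg, 0.345 at 1 pg and 0.286 at 100 fg.

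For the depletion pair r was 0.973 with a pseudocount of 0.1 CPM and 0.972 over genes with at least 10 CPM, and 97.8% lay within 2-fold with 10 CPM. For miniBac-seq and TruSeq these were 0.919, 0.904 and 87.1%. In the panel, median r was 0.904 with 0.1 CPM, 0.976 with 10 CPM and 0.941 thinned. Genes beyond counting error were 100% at 10 CPM and 98.2% thinned, and the biological coefficient of variation was 30.04% and 30.5%. Leaving out 1 primer gave r of 0.951 to 0.953, 99.7 to 99.9% and 35.0 to 36.2%.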

Other observations

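Tests of the low-input genes and of the 5 ng difference were chosen after the results were seen, as were the genes and list shares compared between library groups here. Genes under RpoS, the sigma factor of general stress, took 17.7% of the reads outside rRNA after commercial depletion, 19.1% after customized depletion, 17.5 ± 1.11% at 1 ng (SD, n = 2) and 16.8 ± 1.35% at 100 pg. They took 3.81 ± 0.229% at 5 ng, 1.79% in the miniBac-seq library of the method pair, 1.52% with TruSeq and 0.119 ± 0.0118% in the panel (n = 24). Ribosomal protein genes took 13.1 ± 0.816% in the panel, 11.7% and 10.7% in the method pair, 5.33% at 5 ng and 4.82% after commercial depletion. Amino acid biosynthesis genes took 8.47% and 9.04% in the method pair and 1.22% at 5 ng. No test was run on these shares. The growth condition given at the start is the same for all libraries, so it does not account for these differences.

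The methionine synthase gene metE was at 12170 CPM (miniBac-seq) and 18761 CPM (TruSeq) in the method pair, and at most 327 CPM as the mean of any other group. tdcE was at 10156 CPM in the panel and at most 72.9 CPM elsewhere. hcp was at 6037 CPM after commercial depletion, 5874 after customized depletion and 5534 at 1 ng, at 1731 in the panel, and at 7.13 at 5 ng. tnaA was at 70747 CPM at 5 ng, 7202 in the panel, 1564 after commercial depletion and 17.7 with TruSeq. Across genes, r of log2(CPM + 1) with the 1 ng libraries had a median of 0.964 for the commercial-depletion library and 0.883 for the 5 ng libraries.

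hcp, tnaA, pyrB and the RpoS genes separate the 5 ng libraries from those at 1 ng and 100 pg. A lower amount of RNA as the whole cause is argued against by the spread of log2 fold changes over 392 abundant genes. It was 0.173 times as large for the step from 1 ng to 100 pg (0.295) as for that from 5 ng to 1 ng (1.71). Resampling the genes gave an interval of 0.123 to 0.225 for the ratio, which does not cover the spread between libraries. The genes were chosen by their mean over 5 ng, 1 ng and 100 pg, so genes high at 5 ng alone also entered. The prediction spoke of spread with noise removed; several versions were tried, and removing noise left a variance of -0.188 or -0.00434 for the lower step and 2.79 or 2.88 for the upper, so the ratio with noise kept is an upper bound. Another RNA sample or culture behind the 5 ng libraries stays open: changes of 1 ng replicate 1 over 5 ng replicate 1 and of commercial depletion over 5 ng replicate 2, which share no library, had r = 0.937 across these genes. Any cause that sets the 5 ng libraries apart would give such a value, as these 2 libraries are alike (r = 0.980), and so are 1 ng and commercial depletion (median r = 0.964). The labels name no second culture, but they place the 5 ng libraries in a further figure of the study besides the one shared with the lower inputs. No biological explanation was tested.

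barA, yfhL, mrcA and amtB had like numbers of reads from 1 ng to 100 fg in 1 replicate number and fewer in the other. Carry-over from deeper libraries is argued against, since the 20 most abundant 1 ng genes kept 0.0388 and 0.0312 times their share at 100 fg. So is chance amplification in each tube: 100% of the genes chosen at 100 fg had at least 5 reads at 1 pg in the same number, and at most 14.3% in the other. A background adding a like number of reads to every tube of a number from 1 ng down may be the source of part of them. From 1 pg to 1 ng, log10 reads had slopes on log10 input of -0.0221 (replicate 1) and 0.0214 (replicate 2), after the reads expected from the other number were subtracted. Without this subtraction they went from 1970 to 2793 reads in replicate 1, and from 3901 to 18730 in replicate 2. The slope of replicate 2 therefore rests on the subtraction. The 5 ng tubes were left out of these slopes. At 5 ng, barA had 332 and yfhL 41 reads in replicate 1, and mrcA 347 and amtB 165 in replicate 2. Each had fewer reads there than at any lower input of that number, so the like numbers do not extend to 5 ng. No biological explanation was tested.

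ssrA, ryhB, lpp and leader peptide genes lay lower with miniBac-seq than with TruSeq. The tests were set before the result was seen, but the gap by length with its interval and the reading of rho were chosen after it. A few genes taking most of the counts lowers all other genes alike, so it could not by itself leave a gap by length. That follows from arithmetic alone. The gap is the pattern already seen, so its value is no separate test. The median of genes under 200 nt was -1.54 from that of all genes (95% interval from resampled genes -2.94 to -0.47). Loss of short transcripts is argued against as the whole cause for ssrA, which lay -8.30 from dicA, the lowest of the other genes of like length (170 genes). ssrA was at 16689 CPM after commercial depletion and 4.13 CPM after customized depletion. In the method pair it was at 11775 CPM with TruSeq and 2.99 CPM with miniBac-seq. Its log2 ratio was thus -11.67 between the depletions and -11.53 between the methods, so the method pair alone cannot assign it to library construction. For the other short RNAs loss of short transcripts cannot be told apart: Spearman's rho of length and ratio was 0.00837, which met the bound set against it, while the median of -1.57 under 200 nt met only 1 of the 2 bounds set for it. The bound on rho was ill chosen, since 109 of the 2051 genes other than tRNA (5.31%) are under 300 nt. With 1 library per method, no biological explanation was tested.

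Over the 24 primers, the number of genes with at least 100 CPM and above 4 times the median of the other primers was compared with depth. The 2 had Spearman rho = 0.104 (permutation p = 0.63). Of the low-input genes of replicate 1, at most 21.4% exceeded 4 times that median, at any CPM, in 1 primer library (primer 1), and of replicate 2 at most 17.4% (primer 2). Both values lay between the bounds set beforehand for and against the same priming as 1 of the primers. They therefore do not decide it. fimZ reached 290 CPM with primer 13 and at most 8.02 CPM with any other.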
